A study of Mus musculus with 2 samples.

How the data were processed

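RNA of mouse small intestinal myofibroblasts was measured on the GeneChip Mouse Gene 2.0 ST array, a whole-transcript array that reads a gene with probes along its exons. RNA was extracted with Trizol, purified on columns, amplified and biotin-labelled, per the labels' protocols. Cells were cultured in triplicate and their RNA was pooled, per the series design text, so that each of the 2 conditions has 1 array of 3 pooled cultures. The values used are the authors' deposited log2 values, 1 per probeset and array. Per the submitters' processing notes, Affymetrix Expression Console and RMA were used, and their versions are not given in the sources used here. RMA corrects the background, sets all arrays to one distribution (quantile normalization) and summarises the probes of a probeset. The sorted values of both arrays differed by at most 0.0757, as they do after quantile normalization. This step removes any overall shift between the arrays, so that each difference is relative to all other probesets. The correlation of the arrays across probesets was 0.989, where probesets are not independent replicates.

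Probesets were named from the platform annotation that pairs them with genes. Of 41345 probesets, 23521 were paired with 1 gene, 1814 with several and 16010 with none in that table. The first were used, and the others are described only in the closing section. Gene identifiers of 23328 probesets matched the RefSeq gene table of GRCm38.p6, which gave current symbols, and 193 kept the symbol of the annotation. No coordinates are printed, since the build behind the array values is not given in the sources used here. For 1082 genes with several probesets, the probeset with the highest mean over both arrays stood for the gene. Probesets shared by near-identical genes cannot separate them. The background level was the 95th percentile of 1407 probesets of olfactory and vomeronasal receptor genes on each array. A gene counted as above background when it passed the level on at least 1 array. For a gene under background on 1 array, a fold is given as "at least", computed against the background level of that array. No detection calls were used.

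With 1 array per condition no test between conditions is possible, and no p-value is given. Differences are stimulated minus non-stimulated on the log2 scale, and folds are 2 to the power of their size. Genes were counted past a 2-fold difference. For 21 gene lists, 10 cell type marker lists and 5 groups defined by symbol (ribosomal protein genes, mitochondrially encoded genes, small nucleolar RNAs, microRNA precursors, and olfactory and vomeronasal receptors), the median difference of the members above background was placed among 10000 random lists of the same size. Random members were drawn with replacement from genes in the same of 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5, and lists with under 5 members above background have values only, as was so for 6 of the marker lists. In all, 29 lists were placed. No mitochondrially encoded gene was among the named probesets. Gene lists, thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 12 genes with the largest positive and the 12 with the largest negative difference above background, without predicted, microRNA, small nucleolar, receptor and pseudogene symbols. It added up to 4 members of each list with the largest difference in the direction of the list's median (either direction for a median within 0.1 of 0), the highest 2 members of each marker list, and 13 genes chosen in advance: Csf2, Ccl11, Il33, Tslp, Acta2, Col1a1, Col1a2, Col3a1, Tgfb1, Il6, Ccl2, Timp1 and Mmp3. Some list members are not analysed here.

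The scripts were tested on simulated data built from the 14068 real genes with their differences shuffled among genes of like expression. Of 50 genes changed 3-fold, 49 passed the 2-fold threshold, as did 26 of 50 changed 2-fold and 2 of 50 changed 1.5-fold. The 13868 genes left unchanged held 33 past 2-fold. Since shuffling keeps the large real differences among them, the simulation gives no rate of false passes. Of 200 lists of 20 unshifted genes, 11 stood apart, against 146 of 200 lists shifted by 0.1 and 200 of 200 shifted by 0.2. Shuffling makes the genes independent, as the random lists do, so the 11 were close to what the threshold sets. They give no rate of false calls for lists of genes that vary together. Alternatives were no background filter, a background at the 99th percentile, the mean of a gene's probesets, differences centred on their median or on a lowess trend over expression, thresholds of 1.5-fold and 3-fold, other matching of the random lists, means in place of medians, and lists without their most different member. Added after the data were seen were values under background raised to the background level, and the eosinophil recruitment, ribosomal, contractile and inflammatory lists without some members. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.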

Results

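The series holds 2 arrays of mouse intestinal subepithelial myofibroblasts, the contractile, matrix-producing stromal cells that lie under the gut epithelium. The cells were isolated from the small bowel of wild-type animals of the BALB/c strain. One array holds RNA of cells cultured alone and the other RNA of cells cultured for 1 day with a homogenate of intestinal eosinophils at 5 mg/ml. Eosinophils are granulocytes that reside in large numbers in the small intestine. Cultures were grown in triplicate and their RNA was pooled before labelling, so each condition is 1 array of 3 pooled cultures. There is thus no replicate and no test between the conditions, and every difference given describes these 2 pools, without an error. The number of arrays limits the precision. The comparison addresses which genes differ in myofibroblasts that have met eosinophil material.

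Each array gave log2 values for 41345 probesets. The values ran from 1.08 to 13.79 on the non-stimulated array and from 1.11 to 13.79 on the stimulated array, with medians of 5.76 and 5.77. A background level was read from 1407 probesets of olfactory and vomeronasal receptor genes, and it lay at 5.58 and 5.57 on the non-stimulated and the stimulated array. Of 22180 named genes, 14068 were above it on at least 1 array and 13190 on both.

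The arrays carried the transcripts of fibroblasts. Vim (vimentin) read 13.10 and 13.16 on the non-stimulated and the stimulated array, Acta2 (smooth muscle alpha-actin) read 13.07 and 12.78, and Col1a1 (a chain of type I collagen) read 12.85 and 12.83. All 14 fibroblast identity genes were above background, with a median log2 difference (stimulated minus non-stimulated) of 0.00 between -0.28 and 0.56. One label field names small intestinal eosinophils as the source of both samples, whereas the title and the protocols name myofibroblasts. Of 11 eosinophil markers on the array, 2 were above background on the non-stimulated array and 1 on the stimulated array. The highest of them, Cebpe, reached 5.91 and 5.46, and Alox15 reached 5.68 and 5.87. The granule protein genes Epx and Prg2 were under background on both arrays, at 4.73 and 5.25 for Epx and at 4.75 and 4.32 for Prg2. No marker of mast cells was above background, with Kit highest at 5.40 and 5.12 and Tpsab1 next at 5.15 and 5.20. Of lymphocyte markers 1 of 10 was above it, Cd4 at 5.26 and 5.58, followed by Cd79b at 5.43 and 5.29. Of neutrophil markers 2 of 10 were, Elane at 5.65 and 5.79 and Cxcr2, which differed by 0.07 between the arrays. Of macrophage markers 4 of 15 were, led by Cx3cr1 at 6.57 and 6.81 and Cd68 at 6.31 and 6.52, and of endothelial markers 4 of 10, led by Egfl7 at 6.24 and 6.33 and Pecam1 at 5.87 and 5.83. Of the pan-leukocyte markers, 5 of 12 were above background, and all 5 were lower on the stimulated array, with a median of -0.10. Cd53 was the highest of them, at 9.73 and 9.56, and Cd37 followed at 6.21 and 6.10; their median was at percentile 16.2 of random lists. Of 16 epithelial markers, 5 were above background, led by Krt8 at 6.45 and 6.23 and Muc2 at 5.99 and 6.12, with a median of 0.09 at percentile 86.2. Without the background filter the median of all 16 was -0.17, at percentile 2.15, outside the central 95% of random lists. Enteric neuron and glia markers were above background for 6 of 7 genes, with Uchl1 at 8.62 and 8.51 and Tubb3 at 8.11 and 8.24, and their median was -0.13, at percentile 1.67 of random lists. That place was kept in 4 of 11 alternatives.

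The homogenate went with a small set of large differences, most of them towards higher values. On the stimulated array 27 genes measured at least 2-fold higher and 6 at least 2-fold lower, of 14068 compared. Of these, 9 and 2 were under background on 1 array, and with values raised to the background level, an alternative chosen after the data were seen, the counts were 19 and 4. In all, 97.7% of the genes differed by less than 0.5 on the log2 scale. The genes furthest up were Saa3, an acute-phase serum amyloid A, at 23.7-fold, the neutrophil-attracting chemokine Cxcl5 at 14.7-fold, and the metalloreductase Steap4, which was under background without homogenate and at least 6.78-fold higher with it. Cxcl1, another neutrophil-attracting chemokine, was 7.32-fold higher. They were followed by the matrix metalloproteinases Mmp3 (4.83-fold), Mmp9 (4.29-fold) and Mmp13 (3.26-fold), the long non-coding RNA U90926 (4.15-fold), the copper-carrying ferroxidase ceruloplasmin, Cp (3.82-fold), the eosinophil-attracting chemokine eotaxin, Ccl11 (3.65-fold), and the monocyte-attracting chemokine Ccl2 (2.95-fold). Il13ra2, a decoy cytokine receptor, was under background without homogenate and at least 1.43-fold higher with it.

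The genes furthest down differed less. Ogn (osteoglycin, a small leucine-rich matrix protein) was 2.44-fold lower, Alkal1 (a ligand of the ALK receptor) 2.35-fold, Gucy1a1 (a subunit of the soluble guanylate cyclase that answers to nitric oxide) 2.05-fold and Map3k7cl 2.02-fold lower. Just short of 2-fold were the growth factor Bmp4 (1.96-fold lower), the matrix genes Mgp (1.89-fold) and Aspn (1.86-fold), the collagen-binding integrin Itga11 (1.83-fold), the growth factor Tgfb3 (1.79-fold) and the transcription factor Hey2 (1.78-fold). Cela3a and Zfp772 completed the 12, but both were under background on the stimulated array, which leaves bounds of at least 1.08-fold and 1.35-fold lower. Of 84 olfactory and vomeronasal receptor genes above background, 1 measured at least 2-fold higher (Olfr1394) and 2 at least 2-fold lower (Olfr127 and Olfr667, all 3 named after their values were seen), and they are part of the counts of 27 and 6. These 3 are 3.57% of the receptor genes, while 0.341% of the genes in the dimmest of 4 equal sets by mean expression differed by as much. All 3 were under background on 1 array, and with values raised to that level no receptor gene reached 2-fold. Among the higher genes, 18 of the 27 were above background on both arrays, as were 4 of the 6 lower genes. In these sets of 3517 genes, the central 95% of the differences lay between -0.51 and 0.48 in the dimmest set and between -0.25 and 0.29 in the brightest.

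**Figure D1:**
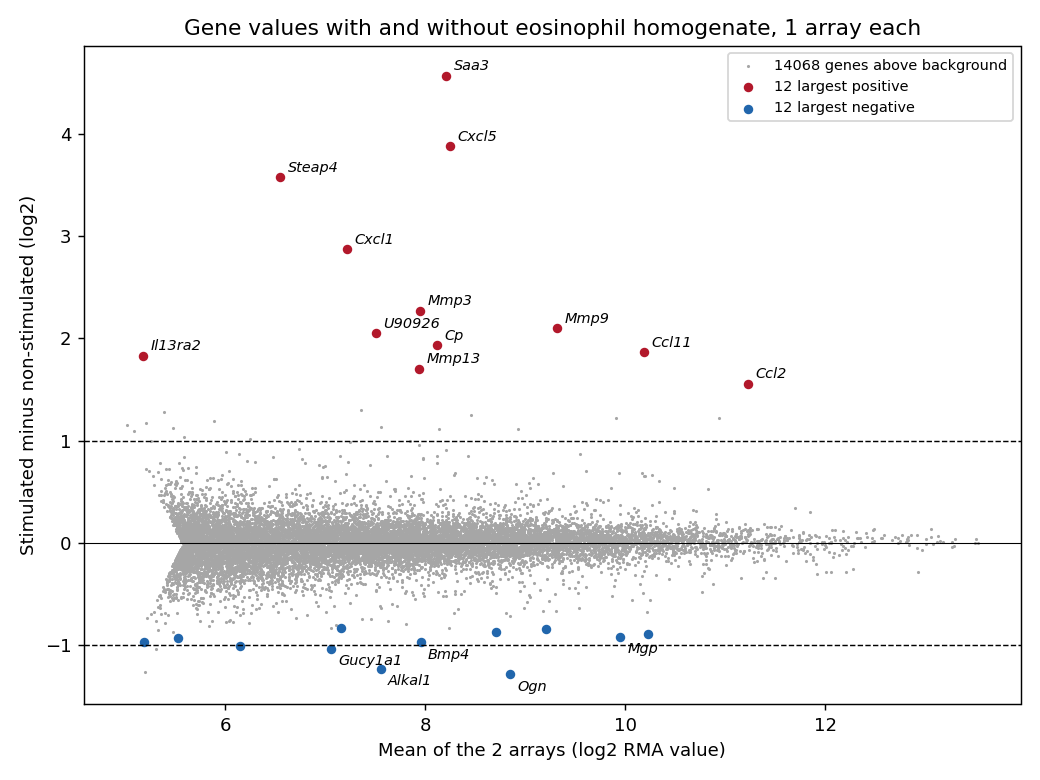
Difference between the stimulated and the non-stimulated array (log2, vertical axis) against the mean of the 2 arrays (log2 RMA value, horizontal axis) for 14068 genes above background. Each point is a gene, the dashed lines mark 2-fold, and the 12 genes furthest up (red) reach further from 0 than the 12 furthest down (blue), with Saa3 at 4.57 and Ogn at -1.29.

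**Figure D2:**
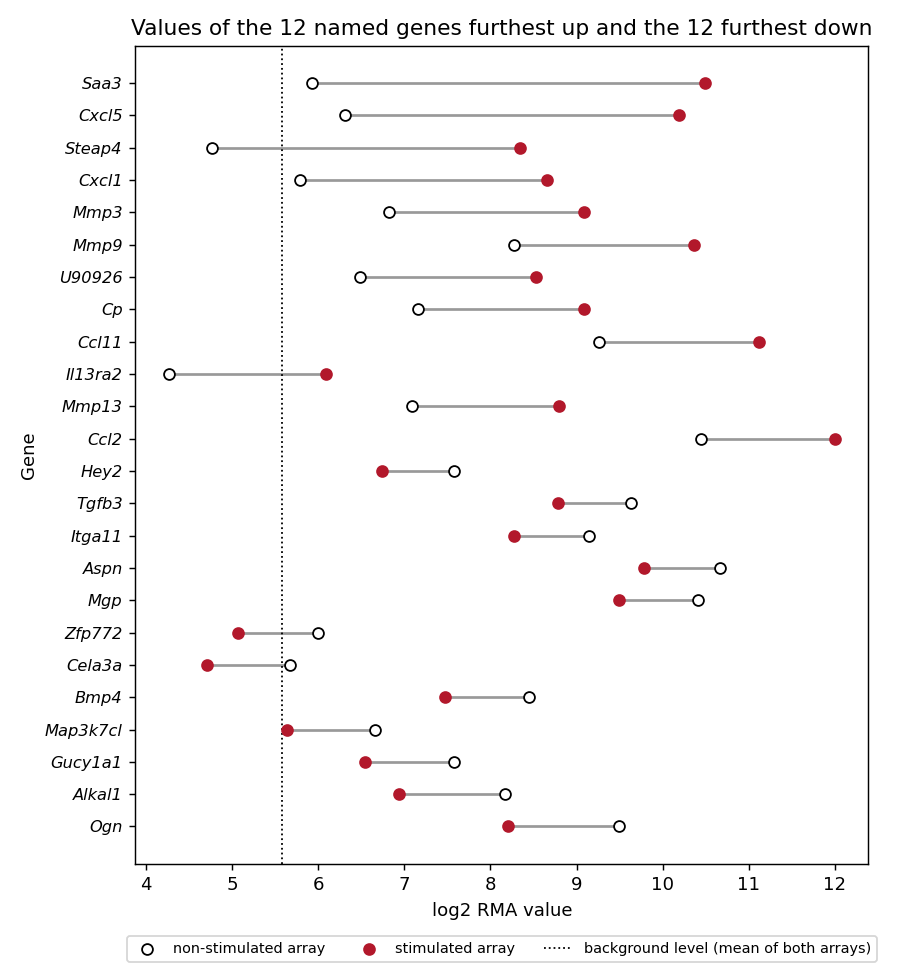
The log2 RMA value (horizontal axis) of the 12 genes furthest up and the 12 furthest down by the naming rule, on the non-stimulated array (open circles) and the stimulated array (red circles), with the background level as a dotted line. Steap4 and Il13ra2 cross the background level upwards and Cela3a and Zfp772 downwards, so that their folds are bounds.

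Inflammatory genes made up the group with the clearest difference. Of 28 members above background in a list of cytokines, chemokines and targets of the transcription factor NF-kB, 24 were higher on the stimulated array, 12 of them by at least 0.5 on the log2 scale and 7 by a measured 2-fold or more, and 3 were lower, none by 0.5. The 7 were Saa3, Cxcl5, Steap4, Cxcl1, Ccl2, the monocyte-attracting chemokine Ccl7 (2.34-fold) and the iron-sequestering protein gene Lcn2, named after its values were seen, which was under background without homogenate. Its bound of at least 1.87-fold leaves 6 members that measured at least 2-fold higher on these 2 arrays with the background level taken into account. Il6, a major inflammatory cytokine, was 1.95-fold higher, from 7.46 to 8.42. Of genes that restrain or tune NF-kB, named after their values were seen, Nfkbia was higher by 0.85 and Nfkbiz by 0.68, while Tnfaip3 read -0.02. The median of the list was 0.34, above all 10000 random lists matched on expression, of which the central 95% lay between -0.05 and 0.06. The upper members did not carry it alone, since the 21 members that measured under 2-fold still had a median of 0.30. Under background on both arrays were 9 members, among them Il1a, Il1b, Tnf, Cxcl2 and Csf2.

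Among eosinophil-attracting and type 2 genes, some chemokines and receptors were higher on the stimulated array and the alarmin Il33 was not. Besides Ccl11 (9.26 and 11.12), Ccl7 and Il13ra2, the chemokine Ccl8 was higher by 0.59 on the log2 scale. Of other members, named after their values were seen, the signalling receptor genes Il13ra1 and Il4ra were 1.49-fold and 1.37-fold higher, and the chemokine Ccl5 differed by 0.01. Also named so, Cish, Arg1 and Socs1 were 1.29-fold, 1.20-fold and 1.09-fold lower, and Socs3 was 1.18-fold higher. Il33 read 7.24 and 6.99, a difference of -0.25. Tslp (4.95 and 4.86) and Csf2, which encodes the growth factor GM-CSF (4.48 and 4.58), were under background on both arrays, so that no difference could be measured for either. Over 14 members above background, 10 were higher and 4 lower. Ccl11 and Ccl7 were at least 2-fold higher, while Il13ra2 measured so but has the lower bound given. The median was 0.15, at percentile 99.9 of random lists. This list shares members with the inflammatory list, and without them its median was 0.05, at percentile 82.0. Without Ccl11 alone it was also 0.05, at percentile 85.4.

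A few matrix-degrading enzymes were higher on the stimulated array, while the median of the list of collagens and other matrix genes was close to 0. Of 23 proteases and inhibitors, 4 were at least 2-fold higher and none at least 2-fold lower. These 4 were the stromelysins Mmp3 and Mmp10 (2.32-fold), the gelatinase Mmp9 (8.27 and 10.37) and the collagenase Mmp13. The inhibitor gene Timp1 read 10.59 and 10.72, a difference of 0.13. The median of the list was 0.05, at percentile 92.9, so that the list as a whole did not stand apart, although its mean of 0.36 did, at percentile 99.99. Ogn, Mgp and Aspn, lower on the stimulated array, were not in the list of collagens and other matrix genes, of which 16 of 33 were higher and 17 lower, with a median of 0.00 at percentile 19.7. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 differed by -0.02, 0.00 and 0.00. Vcan, the proteoglycan versican, was the only list member past 0.5, at 1.45-fold higher, and Col15a1, Thbs1 and Col14a1 were lower by 1.24-fold, 1.22-fold and 1.20-fold.

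Contractile genes were lower as a group, with modest sizes. Of 22 members, 20 were lower on the stimulated array, 4 by at least 0.5 and none by 2-fold. The 4 were the smooth muscle genes Cnn1 (calponin, 1.59-fold lower), Lmod1 (leiomodin, 1.56-fold), Des (desmin, 1.54-fold) and Myh11 (smooth muscle myosin heavy chain, 1.44-fold), and Acta2 was 1.22-fold lower. The median was -0.28, below all 10000 random lists. Genes linked to transforming growth factor beta were lower by less, with 19 of 28 lower and 9 higher and a median of -0.08 at percentile 0.02. Besides Tgfb3, Ccn2 (connective tissue growth factor) was 1.47-fold lower, while Ltbp2 (1.55-fold) and Angptl4 (1.42-fold) were higher. Tgfb1 read 10.22 and 10.12, a difference of -0.10.

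Genes of the oxidative and metal response were higher in 17 of 19 cases, with a median of 0.15 that was above all random lists. The cystine transporter gene Slc7a11 was 2.38-fold higher, the haem-degrading Hmox1 1.58-fold, the transferrin receptor gene Tfrc 1.44-fold and the zinc and iron transporter gene Slc39a14 1.31-fold higher. Other members, named after their values were seen, differed less. The metal-binding protein genes Mt1 and Mt2 differed by 0.04 and 0.05 on the log2 scale and Nqo1 by 0.11, and the 2 lower members were Gstm1 (-0.27) and Osgin1 (-0.10). Cholesterol synthesis genes were higher in 14 of 16 cases, each by little, with a median of 0.12 at percentile 99.99. Lss, Stard4, Insig1 and Fdft1 led them at 1.20-fold, 1.16-fold, 1.16-fold and 1.14-fold.

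Other lists stood apart by small medians. Interferon response genes had a median of 0.08 at percentile 98.8, with 16 of 24 higher. The chemokine Cxcl10 was under background without homogenate and at least 1.49-fold higher with it, and the interferon-induced Ifit1, Gbp3 and Usp18 were 1.42-fold, 1.38-fold and 1.24-fold higher. Cell cycle genes had a median of 0.08 at percentile 99.3, with 27 of 35 higher and none past 0.5. The mitotic genes Kif23, Aurka, Kif11 and Cenpf were 1.36-fold, 1.33-fold, 1.32-fold and 1.21-fold higher. Lipid storage genes had a median of 0.09 at percentile 97.7, with 11 of 13 higher. Fabp4, a fatty acid carrier, was under background without homogenate and at least 1.36-fold higher with it, Fasn (fatty acid synthase) was 1.16-fold higher, and Lpl (1.35-fold) and Plin4 (1.26-fold) were lower. Genes of the unfolded protein and integrated stress response had a median of -0.05 at percentile 1.32, with 16 of 22 lower. Trib3, Sdf2l1, Atf3 and Phgdh were 1.29-fold, 1.23-fold, 1.21-fold and 1.19-fold lower. Each of these 4 lists came inside the central 95% of random lists under at least 1 other setting, the lipid storage list under 4.

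In the remaining lists single genes differed while the medians stayed inside the central 95% of random lists. Among signals of the intestinal niche, which sustain epithelial stem cells, Bmp2 was 2.19-fold, the epithelial growth factor gene Fgf7 2.17-fold and Ereg (epiregulin) 1.60-fold higher, against Bmp4 in the opposite direction, with a median of 0.05 at percentile 93.3. Among purine receptors and ectoenzymes, P2ry6 (1.89-fold) and P2ry2 (1.56-fold) were higher and Entpd1 (1.27-fold) and P2ry1 (1.16-fold) lower, with a median of 0.07 at percentile 91.0. Among eicosanoid genes, the prostaglandin E synthase Ptges was 1.52-fold higher and the cyclooxygenase Ptgs2 1.23-fold higher, Alox5ap was at least 1.24-fold higher and Ptger3 1.22-fold lower, with a median of 0.00 at percentile 52.4. The hypoxia and glycolysis list had a median of 0.04 at percentile 82.8, with Egln3 at 1.46-fold, P4ha2 at 1.34-fold and Bnip3 at 1.19-fold higher and Pfkp at 1.17-fold lower. The heat shock list had a median of 0.07 at percentile 93.0, with Hspb1 1.38-fold lower, Hspe1 at a log2 difference of -0.14, Hsp90aa1 1.13-fold higher and Hspa1a 1.11-fold higher. Immediate early genes had a median of -0.03 at percentile 14.1. Ier3 was 1.83-fold higher there, and Dusp1, Nr4a1 and Dusp5 were 1.22-fold, 1.21-fold and 1.21-fold lower. The p53 list had a median of -0.02 at percentile 14.1, with Fas 1.38-fold, Plk2 1.21-fold and Bbc3 1.13-fold higher and Sesn1 1.22-fold lower. Lysosomal genes had a median of 0.05 at percentile 91.3, and Cd68, Lamp2, Npc1 and Atp6v1h were higher by 0.21, 0.15, 0.14 and 0.12 on the log2 scale. Housekeeping genes had a median of 0.04 at percentile 82.7, and Sdha, Hprt, B2m and Ywhaz differed by 0.08, 0.08, 0.06 and 0.05.

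**Figure D3:**
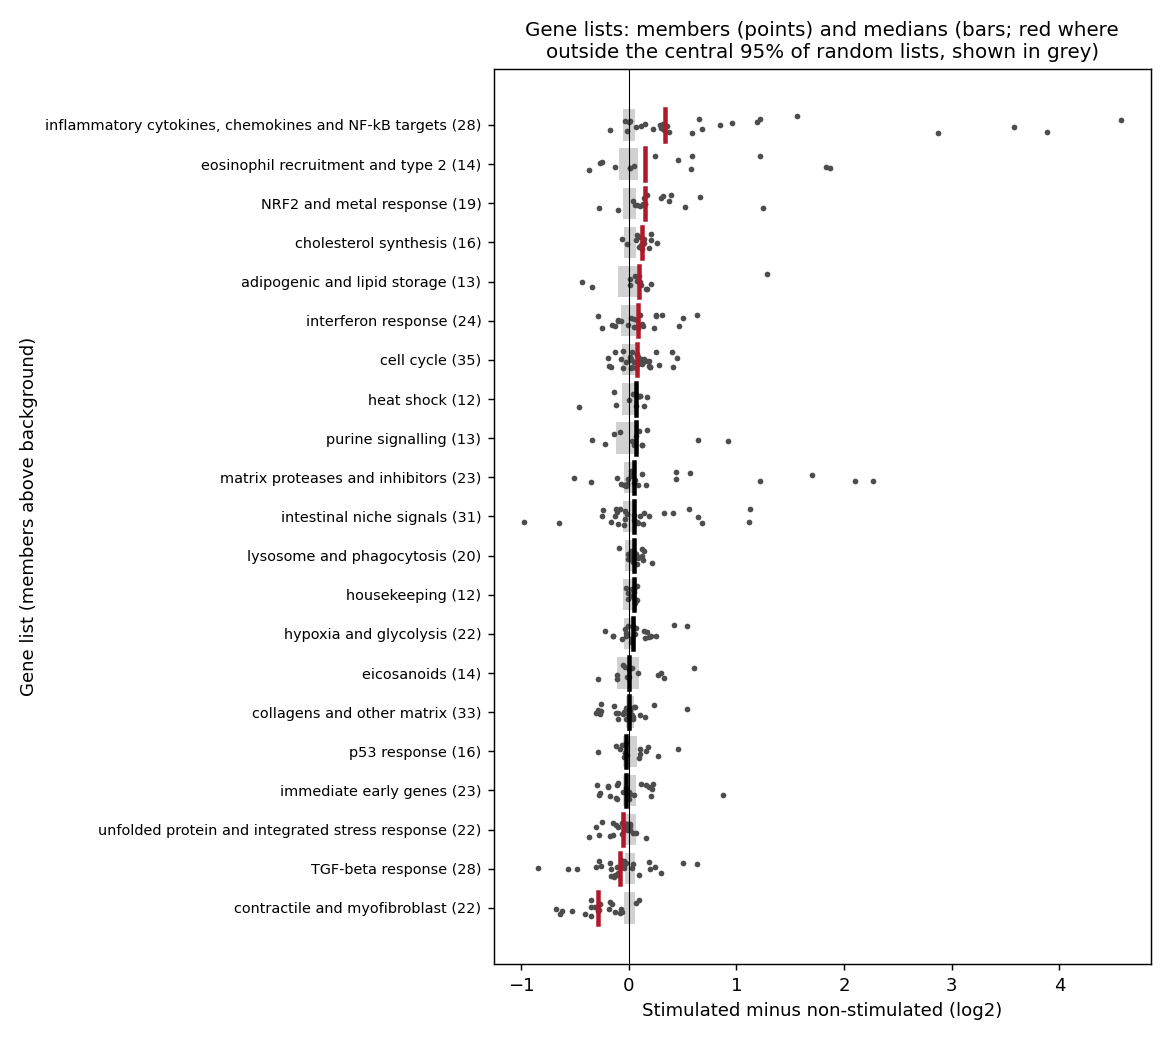
Difference between the stimulated and the non-stimulated array (log2, horizontal axis) for the members above background (points) of 21 gene lists (vertical axis, with the number of members). The vertical bar is the median, drawn in red where it lies outside the central 95% of 10000 random lists (grey), as it does for 10 lists, from 0.34 for inflammatory genes to -0.28 for contractile genes.

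Of the 21 lists, 10 lay outside the central 95% of random lists, where 1.05 would by chance if genes varied independently. The percentiles describe these 2 arrays and treat genes as independent, and pooled RNA gives no replicate error to set beside them.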

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

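Probesets outside the named genes also differed between the arrays. Of the probesets not paired with exactly 1 gene, 110 above background measured at least 2-fold higher on the stimulated array and 45 at least 2-fold lower, where values under background on the other array were taken as they are. Of these, 108 and 45 were among 7550 probesets that the annotation table leaves unnamed, and 2 and 0 among 1081 probesets paired with several genes. The unnamed probesets spread more than named genes did, with a standard deviation of the differences of 0.36 against 0.20. The probesets 17257039 (3.42 and 6.37 on the non-stimulated and the stimulated array) and 17203891 (3.64 and 6.23) were furthest up, and 17391423 (6.17 and 3.62) and 17207091 (5.78 and 3.60) furthest down, each under background on 1 array. Their transcripts are not analysed here.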

How the results depend on the processing

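No paired analysis was possible because each condition has 1 array, and no array could be left out. Where an alternative changed a result, the cause was not tested unless its construction shows it. The count of genes at least 2-fold higher was 43 without the background filter, 112 at 1.5-fold and 11 at 3-fold, and between 19 and 28 otherwise. The count lower was 29 without the filter, 3 with the stricter background, 90 at 1.5-fold and 0 at 3-fold, and between 4 and 7 otherwise. Of the 13 lists that stood apart, 6 did so in every alternative: inflammatory (0.30 to 0.90), oxidative and metal response (0.14 to 0.24), cholesterol synthesis (0.12 to 0.12), contractile (-0.29 to -0.27), transforming growth factor beta (-0.09 to -0.06) and small nucleolar RNA (-0.18 to -0.16). Of the 16 that did not, 12 did so in none. Without the background filter, eosinophil recruitment (0.0587) and interferon response (0.0538) came inside the central range of random lists, and the epithelial marker median turned to -0.1702 and stood apart. With the stricter background, interferon response (0.0644), cell cycle (0.0734) and lipid storage (0.0622) did. Without their most different member, eosinophil recruitment (0.0525), the unfolded protein list (-0.0395) and lipid storage (0.0836) did. Without matching on expression, the unfolded protein list (-0.0508) and lipid storage (0.0911) did, the latter also with the mean of a gene's probesets (0.0911). Means in place of medians put matrix proteases (0.3553), niche signals (0.0937) and purine signalling (0.1117) outside it. Of the alternatives chosen after the data were seen, raising values to background brought interferon response (0.0644) inside, and so did leaving the shared members out of eosinophil recruitment (0.0525). Enteric neuron and glia markers came inside in 7 alternatives, and the receptors without the filter. Of 700 values of named genes, 697 stayed on their side of 2-fold, but most of them could hardly move. The filter settings leave a gene's difference as it is, and centring shifted it by at most 0.0258. Il13ra2 (0.51) and Fabp4 (0.45) fell under 2-fold with values raised to background, and Map3k7cl with the lowess trend removed (-0.99). Raising values to background also took Cela3a from -0.97 to -0.11 and Zfp772 from -0.93 to -0.43, but both were under 2-fold already. Signal over background limits the dim genes most.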

Other observations

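Genes were also grouped into families by the letters of their symbol, some of which overlap the lists. Of 219 families with at least 8 members above background, 28 stood apart from random lists, against 10.95 by chance. The families described were picked after their values were seen. Some others lay as far from 0, among them Klk (-0.21), Car (0.18), Marchf (0.16), Krt (-0.16), Epha (-0.15) and Bmp (-0.15). Other lists already held 6 of 9 Ccl, 4 of 8 Cxcl, 6 of 10 Mcm, 2 of 8 Myl and 15 of 36 Col genes, and none of the Psmd, Casp, Cldn and Itga genes. The Ccl chemokines were higher in 8 of 9 cases and lower in none (median 0.36), and the Cxcl chemokines higher in 5 of 8 (0.38). Regulatory subunits of the proteasome, the Psmd genes, were higher in 12 of 14 cases (0.12). The Casp symbols, mostly caspases, were higher in 8 of 8 (0.14), led by the inflammatory caspase Casp4 at 1.51-fold. The Mcm symbols, mostly genes of DNA replication, were higher in 9 of 10 (0.14), with Mcm3ap the lowest. The claudins of tight junctions were lower in 8 of 10 cases (-0.24), with Cldn1 at 9.21 and 8.49. Integrin alpha chains were lower in 8 of 11 cases (-0.14), with Itga1 1.38-fold lower besides Itga11, and myosin light chains in 7 of 8 (-0.22), with Myl9 1.27-fold lower. The Col symbols were lower in 25 of 36 cases, with a median of -0.05 at percentile 1.88, while the matrix list did not stand apart. Casp4, Cldn1, Itga1 and Myl9 were chosen after their values were seen.

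Named after their values were seen, the other genes that measured at least 2-fold higher were the chemokine Cxcl16 (2.45-fold), the xanthine dehydrogenase Xdh (2.17-fold) and the bradykinin receptor Bdkrb1 (2.02-fold), besides Prnd, Lilrb4a and the predicted genes Gm19792 and Gm8005. The last 4 were under background without homogenate, and their bounds are at least 1.44-fold, 1.04-fold, 1.37-fold and 1.01-fold. Small nucleolar RNAs, which guide the modification of ribosomal RNA, were lower in 55 of 72 cases (median -0.18, below all random lists). Genes with ribosomal protein symbols, which include some Rps6k kinases, did not stand apart (66 genes, 0.01, percentile 50.6), also not without those kinases. Nor did microRNA precursors stand apart (172 genes, 0.00, percentile 62.0). The olfactory and vomeronasal receptors did, at -0.11 and percentile 0.14, with 51 of 84 lower and 31 higher. They also set the background level, which by itself gives no direction, as 71 were above it on each array. Without the background filter their median was -0.04, at percentile 8.16. The median of -0.11 was further from 0 than those of the interferon, cell cycle, lipid storage, transforming growth factor beta and unfolded protein lists. Medians of that size thus also occur in a group used here as background, and the cause was not tested.

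Chosen after the result was seen were the tests of the contractile pattern, of the levels of leukocyte markers, of the genes that contain the small nucleolar RNAs, and of genes of like brightness. For the higher inflammatory values, RNA brought in with the eosinophil homogenate was tested on the eosinophil markers. Their median was -0.071 (95% bootstrap interval over genes -0.43 to 0.13), but 9 of 11 were under background on both arrays, so this median measures little. Their low level argues against carried-over RNA, since 1 of 11 was above background on the stimulated array. More leukocytes in the stimulated cultures were tested on pan-leukocyte markers, with a median of -0.10 (-0.24 to -0.01), though 4 macrophage markers had one of 0.22 (-0.15 to 0.51), with 3 of 4 higher. Most of both lists was under background on both arrays (7 of 12 and 11 of 15) and no macrophage marker passed 6.81. The pan-leukocyte marker Cd53 was well above background, at 9.73 on the non-stimulated and 9.56 on the stimulated array. Both intervals are simply the lowest and the highest value of their few genes. The pan-leukocyte median was also inside the central 95% of random lists, at percentile 16.2. The 5 pan-leukocyte markers above background thus showed no rise, but they are too few to decide on more leukocytes. A small share of macrophages stays open. Marker differences cannot speak to leukocytes that both cultures held alike. A response of the myofibroblasts may be another explanation, and other constituents of the homogenate, such as microbial products, were not tested.

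Contractile genes had a median of -0.28 (95% bootstrap interval -0.35 to -0.16). A smaller share of fibroblasts would lower their other transcripts too, but 12 non-contractile fibroblast markers had a median of 0.00 (0.0026, -0.03 to 0.07) and the 33 matrix genes -0.00 (-0.04 to 0.01), which argues against it. Fewer smooth muscle cells stays open. The 7 members largely restricted to smooth muscle had a median of -0.53 (-0.64 to -0.28), and the 9 that fibroblasts in general express -0.081 (-0.29 to 0.07), an interval too wide to decide. Lower contractile expression within myofibroblasts may be another explanation, as may another cell makeup. Enteric neuron and glia markers were lower too in 5 of 6 cases (median -0.13). Their place outside random lists was kept in only 4 of 11 alternatives, so they say little on cell makeup.

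The small nucleolar RNA median was -0.18 (95% bootstrap interval -0.20 to -0.12). Removing a lowess trend over brightness left it at -0.18 (-0.22 to -0.13), but the trend was nowhere over 0.0258 in size, too small to decide. Random lists of like brightness had medians between -0.02 and 0.04 (central 95%), so genes of like brightness were not lower in general. These are the lists by which the group stood apart, so they add no separate support against a shift by brightness. Lower transcription of the host genes was tested on the RNA levels of 14 Snhg genes, with a median of 0.02 (0.0169, -0.14 to 0.15). That interval overlaps the one of the small nucleolar RNAs, so these genes cannot decide. The 43 genes that contain 57 of the measured RNAs had a median of 0.02 (0.00 to 0.05), which argues against lower RNA levels of those hosts. Transcription itself was not measured. Lower recovery of short RNA stays open, since 15 short RNA genes with other symbols had a median of -0.059 (-0.10 to 0.05), with 11 lower. They include Rnu3a and the Scarna genes, which are related to small nucleolar RNAs, so the set is not wholly separate. No other biological explanation was tested.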
